A study of Mus musculus with 4 samples.

How the data were processed

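The material was MC1-ZE7, a mouse embryonic stem cell line of strain MC1 (129S6/SvEvTac) that carries a reporter in which the fluorescent protein Emerald marks cells transcribing Zscan4. Per the labels' protocols, the cells were grown without feeders in serum and LIF, sorted by Emerald fluorescence, and lysed in Trizol. Total RNA was depleted of ribosomal RNA with a Ribo-Zero Gold kit, made into stranded libraries and sequenced on a HiSeq instrument. Each sorted fraction (Emerald-positive, Em+, the high fraction, and Emerald-negative, Em-) gave 2 libraries, 4 in all. Nothing in the labels says that the 2 libraries of a fraction came from separate cultures or sorts, so p-values measure only the spread between these libraries, which may be technical.

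Groups and replicate numbers were taken from the sample titles. The cell type field names the same fraction as the title in each of the 4 samples, while the description field names the opposite fraction in each of them. The level of Zscan4 transcripts is given first in the results as a check of the titles and was not used to assign any library.

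The authors deposited 4 tables, built on RefSeq, known-gene, ENCODE and Ensembl transcript models, each with 1 line per transcript. Per the file headers each table holds, for every library, a raw count and an FPKM value. The deposited FPKM equals the count divided by the transcript length in kilobases and by a library total, which was recovered from the known-gene table as 36579294 and 37906052 reads for Em+ replicates 1 and 2 and as 35907954 and 37363130 for Em- replicates 1 and 2. Bowtie2 (version not given) and genome build mm10 are named in the submitters' processing notes. The program that counted reads, the release of each annotation, the handling of reads that match several transcripts and the use of strand are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense pairs are therefore uncertain as single entries. Transcripts at 0 in all 4 libraries are not listed in the tables, and transcripts of the mitochondrial genome were not analysed here.

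The count column of Em- replicate 1 holds only 0 in the RefSeq and Ensembl tables, although the deposited FPKM of the same library does not. Counts of this library were computed as FPKM times length times library total, adding 0.0005 since its FPKM is given to 3 decimals and appears truncated, and rounded to the nearest whole read. The library total came from the known-gene table. Applied to the other libraries, which have both columns, with their FPKM truncated to 3 decimals, this calculation returned the exact deposited count for 99.93 to 99.94% of 24538 RefSeq transcripts and for 99.99% of 72703 Ensembl transcripts. The known-gene table does hold counts of Em- replicate 1. The comparison took the 13036 transcripts with the same ID in both tables and identical counts in the other libraries, and left out shared transcripts without such identity. Over these, 99.43% of the computed counts were equal to the known-gene counts, 99.92% were within 1 read, and the largest difference was 7 reads.

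The RefSeq table was the main one. Counts and FPKM were summed over the transcripts of a gene symbol, which gave 19797 symbols. Total counts per library were 17927765 and 16468218 for Em+ replicates 1 and 2 and 18364992 and 18953217 for Em- replicates 1 and 2. The 12050 genes with a mean FPKM of at least 1 over the 4 libraries were tested, and they held 98.61 to 98.99% of each library's counts. The plan fixed before the data were examined had assumed that the tables held FPKM only and named limma on log2(FPKM + 1), with edgeR in its place if counts were found. Because counts were found, the main test was edgeR's quasi-likelihood test (version 4.0.16 in R 4.3.3, glmQLFit and glmQLFTest, TMM scaling, two-sided, no covariate), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The FPKM filter was kept as planned. The common biological coefficient of variation was 0.0731. Levels are given as TMM-scaled CPM of the counts in tested genes, as mean ± SD over 2 libraries, and the SE of a log2 fold change (Em+ over Em-) was taken from the F statistic. Where both Em- libraries had 0 counts, the fold is a lower bound against a floor of 3 counts over the Em- group. Where the Em- total was 1 to 3 counts, the ratio of summed counts is given with an exact 95% binomial interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

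A total of 38 gene lists and families was fixed before the data were examined, from general knowledge of embryonic stem cells and of genes transcribed at the 2-cell stage. They cover 2-cell-stage, pluripotency, chromatin, germ cell, lineage, stress and housekeeping genes and symbol families such as Usp17, Zfp and Gm. The 34 with at least 3 tested members were tested with camera of limma 3.58.1 (preset correlation of 0.01, two-sided, Benjamini-Hochberg over lists). Camera with an estimated correlation and fry were alternatives. A pair of risen genes next to each other in genome order among the tested genes was counted against 10000 random sets of equal size in a one-sided permutation test. The rule for named genes, set before the data were examined, took the 20 largest rises and the 10 largest falls among called genes whose replicates did not overlap between groups, the 4 members of each list with the largest absolute log2 fold change, a short set of marker and control genes, and any gene that an alternative turned round. Genes named outside this rule were named after their values were seen, whether or not this is said beside them. Among them are Lin28a, Tdh, Hist1h2bg, Ier2, Ddit3 and Mir7024.

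On simulated counts drawn for the same 12050 genes and library sizes, with 50 genes changed at each size, the edgeR step recovered 9 of the 50 genes changed 1.25-fold, 38 of those changed 1.5-fold, 46 of those changed 2-fold and 46 of those changed 4-fold, and called 17 of 11850 unchanged genes. The 17 made up a larger share of all simulated calls than the threshold of 0.05. Camera gave an unadjusted p under 0.05 for 5 of 200 unmoved random lists and called the list of 30 genes moved by 0.4 on the log2 scale. Simulated genes were drawn independently of each other, with the same spread assumed for both groups. The simulation therefore cannot tell how camera's preset correlation performs on lists of correlated genes.

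Alternatives chosen before the data were examined were limma on log2(FPKM + 0.1) and log2(FPKM + 0.5), no filter and mean FPKM filters of 0.1 and 5, median-ratio, upper-quartile and quantile scaling, scaling without small RNAs, the highest transcript in place of the sum, limma without a trend, robust fitting, the other 3 tables, the replicate number as a block, a minimum log2 fold change of 1, a test against a log2 fold change of 0.585, and leaving out each library in turn. With 1 library left in a group, that library is assumed to vary like the other group. Limma on log2(FPKM + 1), DESeq2 1.42.0, the filterByExpr filter and scaling by library totals only were added after the data were seen. Limma on the deposited FPKM, which carries no TMM scaling, moves the median log2 fold change of all genes from 0.00 to −0.16 with a pseudocount of 0.1, −0.15 with 0.5 and −0.135 with 1, and its values are read relative to that shift. Coordinates are those of the tables (mm10), written from 1. Gene classes and sequences came from reference annotation of the same build. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.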

Results

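Whole-transcriptome RNA-seq was measured in sorted MC1-ZE7 mouse embryonic stem (ES) cells, in 2 libraries of Emerald-positive (Em+) and 2 of Emerald-negative (Em-) cells. Emerald reports transcription of Zscan4, a gene cluster that is active in 2-cell embryos and in a small, changing fraction of ES cells. The comparison asks which transcripts differ between Zscan4-positive and Zscan4-negative cells. The RefSeq tables held 17927765 and 16468218 counts for Em+ replicates 1 and 2 and 18364992 and 18953217 for Em- replicates 1 and 2. These made up 49.01% and 43.44% of the reads behind FPKM in Em+ replicates 1 and 2, and 51.14% and 50.73% in Em- replicates 1 and 2. The 2 Em+ libraries differed from each other by more than the 2 Em- libraries did, with a chi-square per degree of freedom of 35.1 against 4.31. Both values lie above 1, so no library was a repeat of another within sampling noise. Rn45s, a model of ribosomal RNA precursor sequence, took 7.95% of the counts of Em+ replicate 2. It took 3.93%, 4.33% and 3.98% of those of Em+ replicate 1 and Em- replicates 1 and 2.

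Zscan4 transcripts were abundant in both Em+ libraries and close to absent from both Em- libraries. Genes of the cluster encode zinc finger and SCAN domain proteins, although Zscan4a is annotated as a transcribed pseudogene. The 6 listed members together reached 212 and 224 CPM in Em+ replicates 1 and 2. They reached 1.81 and 2.27 CPM in Em- replicates 1 and 2, a 107-fold difference of the means. Zscan4d, on chromosome 7 from 11161643 to 11166148, was the most abundant member at 91.4 ± 2.52 CPM in Em+ cells and 1.29 ± 0.0377 CPM in Em- cells (SD, n = 2 each). Its log2 fold change was 6.14 (SE 0.11, adjusted p = 2.74e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Zscan4a (chromosome 7, 10794241 to 10799065) rose from 0.399 ± 0.331 to 70.6 ± 5.98 CPM, a log2 fold change of 7.42 (SE 0.24, edgeR adjusted p = 2.63e-06). Zscan4c (chromosome 7, 11005745 to 11010547) rose from 0.268 ± 0.0681 to 40.7 ± 2.21 CPM, a log2 fold change of 7.20 (SE 0.19, edgeR adjusted p = 1.04e-06). Zscan4b, Zscan4e and Zscan4f lay below the expression filter. Zscan4b had 42 and 56 counts in the Em+ libraries and 0 in both Em- libraries, which makes it at least 35.95-fold higher. All 3 tested members of the list rose, also when adjusted over the list alone, and camera called the list (adjusted p = 2.02e-95, and adjusted p = 0.0375 with an estimated correlation). Members of the cluster are near-identical in sequence, so their single values are less certain than the sum. The value of Zscan4a rests on few Em- reads and was 6.78 without Em- replicate 1 and 8.68 without Em- replicate 2. The order of the groups went with the titles and against the description field in all 4 libraries.

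**Figure D1:**
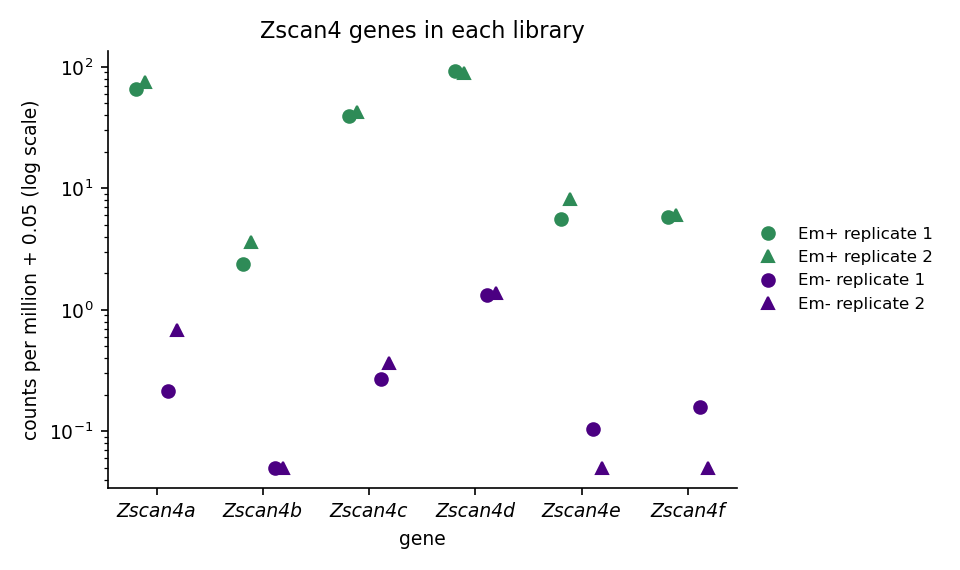
Levels of the Zscan4 genes in each of the 4 libraries, in CPM on a log axis, with the Em+ and Em- groups marked. The Em+ libraries sum to 212 and 224 CPM and the Em- libraries to 1.81 and 2.27 CPM.

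Of 12050 genes tested, 460 were higher and 99 were lower in Em+ cells, 559 in all or 4.64% (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 3045 genes. In all 559 the values of the 2 groups did not overlap. Calls on these same libraries largely select for this, so it is no further support. Among genes that are not selected, chance alone gives it for 33.3% with 2 libraries against 2. The rises were larger than the falls. A log2 fold change of at least 1 was reached by 170 of the risen genes and by 2 of the fallen genes in their direction, and 59 risen genes reached at least 3. The median log2 fold change was 0.78 among risen genes, −0.43 among fallen genes and 0.00 over all tested genes. Among the risen genes 430 were protein-coding, 14 were long non-coding RNAs, 10 were transcribed pseudogenes and 3 were microRNAs. The number of calls depended on which library was used to estimate the spread. Leaving out Em+ replicate 1 gave 4992 calls (2642 higher, 2350 lower), leaving out Em+ replicate 2 gave 1968 (1136 higher, 832 lower), and all 559 genes were called in the same direction in both fits. Leaving out Em- replicate 1 gave 490 calls (457 higher, 33 lower), which held 328 of the risen and 24 of the fallen genes. Leaving out Em- replicate 2 gave 587 calls (514 higher, 73 lower), which held 355 of the risen and 32 of the fallen genes.

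**Figure D2:**
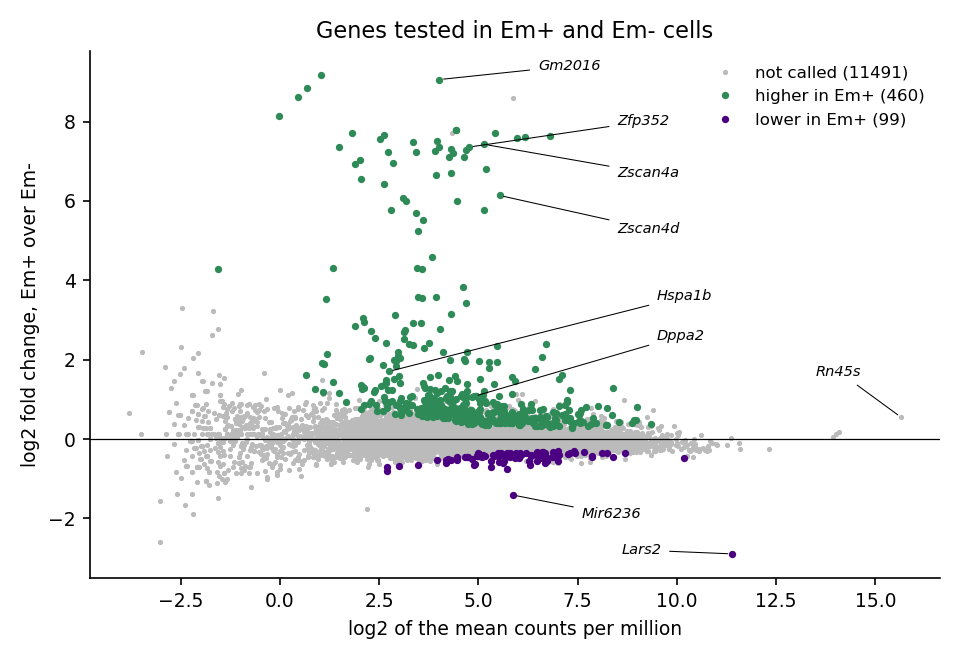
Log2 fold change (Em+ over Em-) of each of the 12050 tested RefSeq genes against its mean level, with called genes marked. The 460 risen genes reach log2 fold changes above 9, whereas only 2 of the 99 fallen genes, Lars2 and Mir6236, lie at or below −1.

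The largest rises were in genes with almost no reads in Em- cells. Gm2016, one of a group of related genes on chromosome 12 (87874072 to 87877859), rose from 0.0538 ± 0.0016 to 32.4 ± 1.53 CPM, with a log2 fold change of 9.06 (SE 0.24, edgeR adjusted p = 1.04e-06). Its Em- libraries held 2 reads in all, which gives a 604-fold ratio of counts with a counting interval from 167 to 4991. Zfp352, a zinc finger gene known as a marker of 2-cell embryos (chromosome 4, 90218820 to 90225687), rose 167-fold from 0.323 ± 0.0096 to 54.0 ± 1.55 CPM, a log2 fold change of 7.36 (SE 0.15, edgeR adjusted p = 3.59e-07). Gm8300 was the most abundant of the 20 largest rises at 222 ± 2.07 against 1.09 ± 0.690 CPM, and it was followed by Gm5039 at 144 ± 2.92 against 0.723 ± 0.245 CPM. D17Ertd648e, Defb25, Esp24 and Mir8109 had no read in either Em- library and were at least 50.3-fold, 40.0-fold, 34.1-fold and 24.6-fold higher in Em+ cells. Defb25 belongs to the beta-defensins and Esp24 to the exocrine gland-secreted peptides. The rest of the 20 were Usp17lc, BC147527, Gm4971, Gm4027, Usp17la, Gm8994, Gm5662, Pramef25, Abcb5, Zscan4a, Tcstv3 and Gm8764, and over the 16 genes with Em- reads the fitted log2 fold changes ran from 7.35 to 9.06. Leaving out an Em- library moved 10 of these 16 by more than 1.5 times, to between 6.41 (Tcstv3 without Em- replicate 1) and 12.1 (Tcstv3 without Em- replicate 2).

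Genes transcribed at the 2-cell stage rose as a group in Em+ cells. Of the 38 tested members of the list, 32 rose and none fell over all genes tested, and 33 were higher and 1 was lower when adjusted over the list alone. No tool called a member lower over all genes (DESeq2 0, limma on log2(FPKM + 1) 0), and 1 was lower at an unadjusted p under 0.05. Their median log2 fold change was 6.74. It was 2.62 over the 16 members with mostly unique sequence and 7.27 over the 22 with sequence shared among copies. Camera's adjusted p was too small to be represented and printed as 0, and adjusted p = 0.0135 with an estimated correlation. Fgf1, a fibroblast growth factor, rose from 4.41 ± 0.325 to 47.6 ± 0.4 CPM, Arg2, a mitochondrial arginase, rose from 1.70 ± 0.0124 to 20.5 ± 1.22 CPM, and Nelfa, a subunit of the negative elongation factor of RNA polymerase II, rose from 33.3 ± 2.21 to 175 ± 9.84 CPM (these 3 members were chosen after their values were seen). A further 26 listed members lay below the expression filter. Of these, 24 had more reads in the Em+ than in the Em- libraries and 9 had none in Em- cells. Dux, a homeobox gene that activates 2-cell-stage genes, had 46 and 44 counts in the Em+ libraries and 1 and 6 in the Em- libraries. Tcstv1 had 12 and 17 counts against 0 in both.

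Several multigene families followed, but their lists overlap the 2-cell-stage list and are not separate evidence. All 5 tested Usp17 genes, Pramef25, Pramef8, Pramef12, Zfp352, Zfp809 and some Gm models are members of both. All 5 tested Usp17 genes, which encode deubiquitinating enzymes, rose, 5 also when adjusted over the list alone, with a median log2 fold change of 7.26 (camera adjusted p = 1.17e-77, and adjusted p = 0.110 with an estimated correlation). Of 4 tested Pram family genes 3 rose, the same number when adjusted over the list alone (camera adjusted p = 1.17e-12, and adjusted p = 0.148 with an estimated correlation). They were Pramef25 at 7.52, Pramel1 at 1.36 and Pramef8 at 0.64 on the log2 scale, while Pramef12 at 0.07 (edgeR adjusted p = 0.638) did not pass, except without Em+ replicate 2 (0.18, adjusted p = 0.0392). Camera did not call the Pram list in the Ensembl (adjusted p = 0.244) or ENCODE (adjusted p = 0.210) tables, and over its 24 alternatives the adjusted p ran from 1.31e-15 to 0.244. Among 187 predicted gene models with Gm names 28 rose and 1 fell, 41 and 5 when adjusted over the list alone (camera adjusted p = 8.96e-18, and adjusted p = 0.189 with an estimated correlation), and camera did not call this list in the Ensembl (adjusted p = 0.341) or ENCODE (adjusted p = 0.0584) tables. Its median of 0.17 was 0.09 without Em+ replicate 2, and over its 25 alternatives the adjusted p ran from 1.73e-20 to 0.341. Of 284 Zfp genes 20 rose and none fell, 28 and 0 when adjusted over the list alone, and 12 were lower at an unadjusted p under 0.05 (DESeq2 0 lower, limma 0 lower). Zfp560 (log2 fold change 2.01), Zfp809 (1.38), a repressor of retroviral sequences, and Zfp677 (1.04) came after Zfp352. The median of the Zfp list was small at 0.09, was negative on deposited FPKM without further scaling (−0.06 with a pseudocount of 1, above the all-gene median of −0.135 there), and camera's adjusted p = 0.0274 became adjusted p = 0.708 with an estimated correlation. The call was also lost without Em+ replicate 2 (adjusted p = 0.0858) and without Em- replicate 1 (adjusted p = 0.0527), and over its 25 alternatives the adjusted p ran from 0.00766 to 0.708.

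In smaller families few genes rose, by amounts that ranged from small to large. Olfr376, Tdpoz4 and Obox6 are also members of the 2-cell-stage list. Of 8 olfactory receptor genes Olfr376 and Olfr1372-ps1 rose (3 when adjusted over the list alone), with log2 fold changes of 6.92 and 1.97. Camera called that list (adjusted p = 1.04e-04, and adjusted p = 0.470 with an estimated correlation), and fry did not (adjusted p = 0.101). Olfr376 had 2 reads in all in Em- cells, a 137-fold ratio of counts with a counting interval from 37.5 to 1138, and its log2 fold change was 6.03 without Em- replicate 1 and 9.997 without Em- replicate 2. Of 33 Trim genes, which encode RING-domain ubiquitin ligases, Trim75 (6.01, and 6.80 without Em- replicate 2) and Trim12c (0.63) rose and Trim2 (−0.57) fell, with 3 higher and 1 lower when adjusted over the list alone. Camera did not call that list (adjusted p = 0.590) but fry did (adjusted p = 0.00783), and Trim12c lost its call without Em- replicate 1 (adjusted p = 0.0658). Rhox13 rose among 4 reproductive homeobox genes (log2 fold change 0.75, 2 when adjusted over the list alone). Camera's adjusted p = 0.0994 for the Rhox list passed without Em+ replicate 2 (adjusted p = 0.00749) and without Em- replicate 1 (adjusted p = 0.0454), and over its 24 alternatives ran from 0.00749 to 0.708. Maged1 rose among 5 Mage genes (0.38, 1 when adjusted over the list alone, list adjusted p = 0.480) and lost its call without Em- replicate 1 (adjusted p = 0.281) or Em- replicate 2 (adjusted p = 0.163). The Tdpoz, Obox and Hox families had 1 tested member each and were not tested as lists. Tdpoz4 rose with a 102-fold ratio of counts (counting interval 34.7 to 499), Obox6 rose with a log2 fold change of 2.85 (3.44 without Em- replicate 2), and Hoxc13 stood at 0.08.

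**Figure D3:**
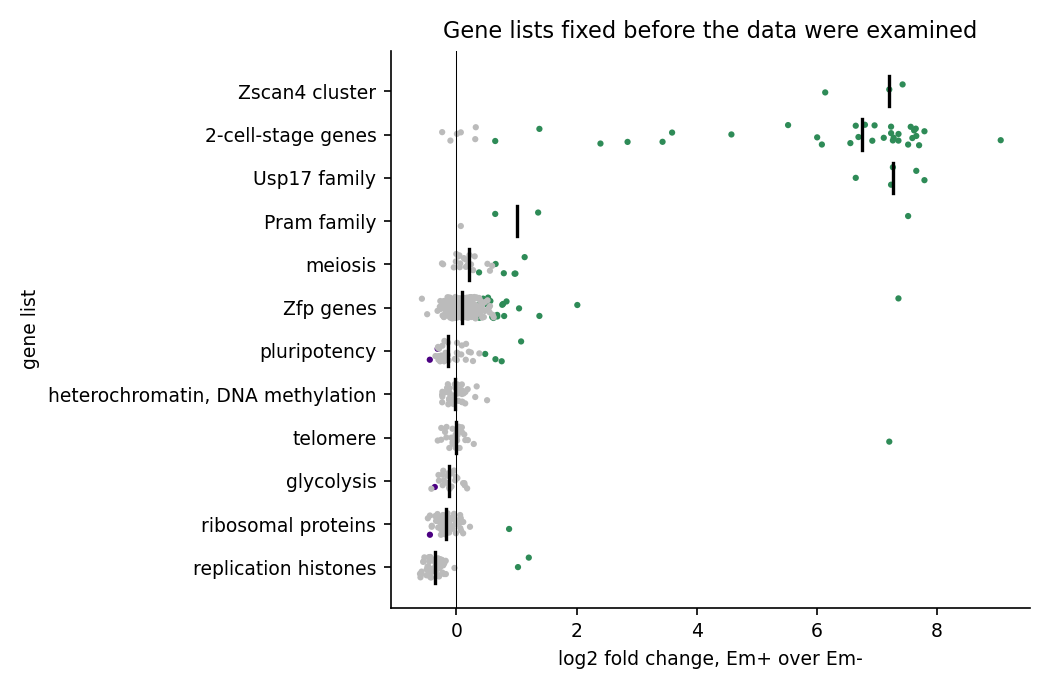
Log2 fold change (Em+ over Em-) of the tested members of gene lists fixed before the data were examined, with the median of each list. The Zscan4, Usp17 and 2-cell-stage lists have medians of 7.20, 7.26 and 6.74, while the replication histone and ribosomal protein lists have medians of −0.35 and −0.18.

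Pluripotency genes changed little and in both directions. Of 38 tested members 4 rose and 2 fell, with 6 higher and 10 lower when adjusted over the list alone, and camera did not call the list (adjusted p = 0.408). Dppa2, a chromatin-associated factor of pluripotent cells, rose from 19.1 ± 0.760 to 40.3 ± 0.581 CPM (log2 fold change 1.08, SE 0.08, edgeR adjusted p = 2.52e-04). Fbxo15 rose by 0.75, Tbx3 by 0.65 and Nanog by 0.48 on the log2 scale, Nanog from 403 ± 13.6 to 561 ± 46.5 CPM (edgeR adjusted p = 0.0192). Lin28a and Tdh, the threonine dehydrogenase of ES cells, fell, with log2 fold changes of −0.44 and −0.31. Pou5f1 (693 CPM in Em+ against 837 CPM in Em- cells, log2 fold change −0.27, edgeR adjusted p = 0.161), Sox2 (−0.29, adjusted p = 0.0933) and Zfp42 (0.02, adjusted p = 0.902) did not pass. The calls near the threshold turned on single libraries. Nanog was not called without Em- replicate 1 (adjusted p = 0.211) or Em- replicate 2 (adjusted p = 0.0714), and 7 of its 25 alternatives did not call it. Pou5f1 and Sox2 were called lower without Em+ replicate 1 (−0.42 and −0.35, adjusted p = 2.96e-05 and 3.41e-05) and without Em+ replicate 2 (−0.14 and −0.23, adjusted p = 0.0259 and 0.00132).

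No gene of heterochromatin or DNA methylation passed the test. Of 42 tested members edgeR called 0, also when adjusted over the list alone, with 7 at an unadjusted p under 0.05; DESeq2 called 1 (Kdm5b, higher) and limma on log2(FPKM + 1) called 0, and camera did not call the list (adjusted p = 0.413). Dnmt1, the maintenance DNA methyltransferase, and its partner Uhrf1 had log2 fold changes of −0.12 (SE 0.06, edgeR adjusted p = 0.259) and −0.11 (SE 0.06, adjusted p = 0.308). Dnmt3b and Dnmt3l stood at −0.12 (adjusted p = 0.268) and −0.12 (adjusted p = 0.379). The members with the largest values were Hdac1 (0.51, adjusted p = 0.114), Tet1 (0.34, adjusted p = 0.207), Kdm5b (0.31, adjusted p = 0.0803) and Chaf1b (−0.24, adjusted p = 0.101). Without Em+ replicate 1 all 8 of these genes passed, Dnmt1 at −0.16 (adjusted p = 0.0112), Uhrf1 at −0.15 (0.0101), Dnmt3b at −0.14 (0.0368), Dnmt3l at −0.21 (0.00103), Hdac1 at 0.73 (3.82e-04), Tet1 at 0.56 (1.61e-06), Kdm5b at 0.40 (4.54e-05) and Chaf1b at −0.28 (0.00213). Kdm5b (0.22, adjusted p = 0.00462) and Chaf1b (−0.20, adjusted p = 0.0241) also passed without Em+ replicate 2.

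Some genes of meiosis rose in Em+ cells, and most did not pass the test. Of 26 tested genes of meiosis and recombination 6 rose and none fell, with 8 higher and 1 lower when adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05 (DESeq2 0 lower, limma 0 lower). Camera called the list (adjusted p = 0.0032, and adjusted p = 0.708 with an estimated correlation), and fry did not (adjusted p = 0.101). The 6 were Sycp1 and Syce1, components of the synaptonemal complex, the RNA-binding protein gene Dazl, Taf7l, Mael and Ddx4. Dazl rose from 101 to 199 CPM, a log2 fold change of 0.98 (SE 0.06, edgeR adjusted p = 1.20e-04), and the values of Sycp1, Taf7l and Syce1 were 1.13, 0.97 and 0.79. Mael (0.65) was not called without Em- replicate 1 (adjusted p = 0.0613), nor was Ddx4 (0.38) without Em- replicate 1 (adjusted p = 0.238) or Em- replicate 2 (adjusted p = 0.211); these 2 were named after their values were seen. Of 6 tested oocyte genes Nlrp4f (0.80) and Nlrp14 (0.70) rose, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.413). Among 19 imprinted genes Peg10, a gene of retrotransposon origin, rose by 0.81 on the log2 scale (2 higher when adjusted over the list alone, camera adjusted p = 0.616). In the telomere list of 31 tested genes the single risen member, also when adjusted over the list alone, was Zscan4c itself (camera adjusted p = 0.590, fry adjusted p = 0.0272), and 2 members were lower at an unadjusted p under 0.05.

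Replication-dependent histone genes and ribosomal protein genes lay lower in Em+ cells as groups, by small amounts. The median log2 fold change of 60 histone genes was −0.35, and camera called the list (adjusted p = 1.95e-09, and adjusted p = 0.708 with an estimated correlation). Over all genes 1 histone gene fell, Hist1h2bg (−0.47). Of the list 2 rose, Hist1h2ba (1.20) and Hist1h2aa (1.02), both known as testis-specific variants. Adjusted over the list alone 35 were lower and 2 higher, and 43 were lower at an unadjusted p under 0.05. DESeq2 called 22 lower and limma called 0 lower. Among the 82 ribosomal protein genes, with a median of −0.18, Rpl22l1 fell (−0.44) and Rpl10l, a retrotransposed copy of Rpl10, rose (0.88), with 1 higher and none lower when adjusted over the list alone, 25 lower at an unadjusted p under 0.05 (DESeq2 2 lower, limma 1 lower, Rps21). Camera called that list (adjusted p = 1.12e-04, and adjusted p = 0.708 with an estimated correlation). Fry called neither that list (adjusted p = 0.101) nor the histone list (adjusted p = 0.254). Rpl22l1 lost its call without Em- replicate 1 (adjusted p = 0.319) or Em- replicate 2 (adjusted p = 0.0983). Without Em+ replicate 2, the library with the highest Rn45s share at 7.95%, the medians were −0.29 and −0.13, and camera still called both lists. The histone median was −0.21 without Em- replicate 1.

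Genes of energy metabolism, protein turnover and growth showed shifts at or below the threshold. Of 23 glycolysis genes Ldhb fell (−0.36), 3 were lower when adjusted over the list alone, and camera's adjusted p was 0.0410, against adjusted p = 0.708 with an estimated correlation. The proteasome list of 42 genes had a median of −0.09 and camera's adjusted p was 0.0428, against adjusted p = 0.708 with an estimated correlation. No proteasome gene was called by edgeR, DESeq2 or limma, nor when adjusted over the list alone, and 7 had an unadjusted p under 0.05. Both list calls were lost without Em+ replicate 2 (adjusted p = 0.0770 and 0.279) and without Em- replicate 2 (adjusted p = 0.0633 and 0.0803), with medians of −0.05 and −0.01 without Em+ replicate 2. Over their 25 alternatives the adjusted p ran from 8.53e-05 to 0.708 and from 4.69e-05 to 0.708. Ldhb was not called without Em- replicate 1 (adjusted p = 0.189) or Em- replicate 2 (adjusted p = 0.164). Among 41 cell cycle genes Cenpe, a kinetochore motor, rose (0.35, 1 higher and 2 lower when adjusted over the list alone), but not without Em- replicate 1 (adjusted p = 0.429) or Em- replicate 2 (adjusted p = 0.189). Of 39 translation initiation genes, 49 splicing genes and 25 targets of p53, edgeR called none, also when adjusted over the list alone, with 8, 10 and 7 at an unadjusted p under 0.05. DESeq2 called Eif4g2 and Rbm25 higher and Bbc3 lower, and limma called none. Camera did not call the cell cycle, translation, splicing or p53 lists (adjusted p = 0.128, 0.190, 0.254 and 0.0994). Without Em+ replicate 1 it called the cell cycle, translation and p53 lists lower (adjusted p = 0.0269, 0.0312 and 0.0307), and Eif4g2, Rbm25 and Bbc3 then passed in edgeR (adjusted p = 2.24e-05, 4.03e-05 and 0.00208), as they did without Em+ replicate 2 (adjusted p = 0.00640, 2.51e-04 and 0.0266). Srrm2, the splicing gene with the largest value (0.74, edgeR adjusted p = 0.0955), passed without Em+ replicate 1 (1.07, adjusted p = 2.10e-08), Em+ replicate 2 (0.30, adjusted p = 2.65e-04), Em- replicate 1 (adjusted p = 0.0112) and Em- replicate 2 (adjusted p = 0.00569).

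The largest falls were few and led by Lars2 and Mir6236. Lars2, the mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123366940 to 123462664), had 634 ± 543 CPM in Em+ and 4715 ± 2174 CPM in Em- cells, a log2 fold change of −2.89 (SE 0.61, edgeR adjusted p = 0.0444). Its value was −4.24 without Em+ replicate 1 and −2.21 without Em+ replicate 2, and 6 of 25 alternatives did not call it, with adjusted p from 4.20e-29 to 0.271 over all 25. Mir6236 (chromosome 9, 110281287 to 110281409) had 32.0 ± 2.91 against 85.1 ± 25.8 CPM, a log2 fold change of −1.41 (SE 0.19, edgeR adjusted p = 0.00667). Ntn1, which encodes the guidance factor netrin-1, fell from 67.0 ± 4.24 to 39.4 ± 2.04 CPM (log2 fold change −0.76, SE 0.09, edgeR adjusted p = 0.00228). Inhbb, an inhibin and activin subunit gene, Gpx2, a glutathione peroxidase gene, and Dpys, a dihydropyrimidinase gene, had log2 fold changes of −0.70, −0.66 and −0.66. Zmynd10 (−0.81), Rgs11 (−0.69), AI467606 (−0.67) and Gbe1 (−0.64) completed the 10 largest falls. Zmynd10, Rgs11 and AI467606 were not called without Em- replicate 1 (adjusted p = 0.116, 0.220 and 0.0929), and Gbe1 was not called without Em- replicate 2 (adjusted p = 0.0529).

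Camera called no list of markers of other cell types, although 2 fibroblast markers rose. Of 7 ectoderm or primed-state, 5 mesoderm, 10 endoderm and 10 trophectoderm genes edgeR called none, with 2, 0, 2 and 3 at an unadjusted p under 0.05, and 1 ectoderm gene higher, 1 ectoderm gene lower and 1 endoderm gene higher when adjusted over the list alone. DESeq2 called Otx2 lower, as edgeR did without Em+ replicate 1 (adjusted p = 1.60e-04) or Em+ replicate 2 (adjusted p = 0.00853), and limma called none. Camera called none of the 4 lists (adjusted p = 0.918, 0.616, 0.413 and 0.814). Of 9 fibroblast markers the surface antigen gene Thy1 (0.89) and the collagen gene Col5a1 (0.85) rose, 2 also when adjusted over the list alone, and camera did not call the list (adjusted p = 0.287) except with no filter (adjusted p = 0.00962), with a range from 0.00962 to 0.879 over its 25 alternatives. Of 29 genes of sorting stress the heat shock gene Hspa1b rose 3.26-fold, and Ier2, Ddit3, Jund and Junb fell, with 3 higher and 8 lower when adjusted over the list alone. Camera's adjusted p = 0.151 for the stress list became 0.0355 without Em+ replicate 1, and Junb and Jund were not called without Em- replicate 1 (adjusted p = 0.271 and 0.449). Of 15 genes of interferon and viral sensing edgeR called none, with 1 higher and 3 lower when adjusted over the list alone and 5 at an unadjusted p under 0.05, while DESeq2 called Ifitm1 lower, as edgeR did without Em+ replicate 1 (adjusted p = 1.43e-04) or Em+ replicate 2 (adjusted p = 0.00598), and limma called none (camera adjusted p = 0.198). Camera's direction and the sign of the median differed for the ectoderm, trophectoderm, telomere and microRNA lists, none of which camera called; fry called the telomere list (adjusted p = 0.0272).

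Among 18 housekeeping genes Polr2a, the largest subunit of RNA polymerase II, was the 1 that rose, also when adjusted over the list alone, where 1 other was lower (camera adjusted p = 0.103). Polr2a stood at 206 ± 111 CPM in Em+ and 67.3 ± 7.36 CPM in Em- cells, and its log2 fold change of 1.61 was 0.92 without Em+ replicate 2. Of its 25 alternatives 6 did not call Polr2a, with adjusted p up to 0.219. DESeq2 did not call Polr2a and called Pgk1 lower, while limma on log2(FPKM + 1) called Polr2a higher. Actb (−0.16, edgeR adjusted p = 0.391), Gapdh (−0.22, adjusted p = 0.265), Hprt (−0.15, adjusted p = 0.191) and Tbp (0.03, adjusted p = 0.844) did not pass. Actb (adjusted p = 2.43e-04) and Hprt (adjusted p = 0.00487) were called lower without Em+ replicate 1, and Gapdh (adjusted p = 0.00153) without Em+ replicate 2. Of 113 small nucleolar RNA genes edgeR called none, also when adjusted over the list alone, with 11 at an unadjusted p under 0.05, and DESeq2 and limma called none (camera adjusted p = 0.402). Of 568 microRNA genes Mir8109, Mir466f-1 and Mir7024 rose and Mir6236 fell, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.590, and a median of 0.04 that is the same with Mir8109 at its lower bound). Limma on log2(FPKM + 1) called 25 higher and 33 lower in this list. Mir466f-1 had 1 Em- read and was not called without Em- replicate 1 (adjusted p = 0.0867). The libraries held fragments of 130 to 290 bases, so reads in microRNA genes do not count mature microRNAs. Of the 34 lists tested, some of which share members, camera called 12 and fry called 7. Camera with an estimated correlation called 2, the Zscan4 and 2-cell-stage lists. The list of mitochondrially encoded genes had no member in the table and was not analysed here.

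Risen genes lay next to each other in the genome more often than random sets of genes did. There were 56 pairs of neighbours that both rose, against a mean of 17.5 and a maximum of 37 in 10000 random sets of 460 tested genes (one-sided permutation test, p = 1e-04, the smallest value these permutations can give). The pairs formed 43 runs with 99 genes, of which 6 runs held at least 3 genes. The longest, on chromosome 12 from 87514316 to 88321762, held 7 genes in 807 kb (Gm8300, Gm4027, Gm1995, Gm2016, Gm2022, Gm5662 and Gm5039) with a median log2 fold change of 7.62. A run on chromosome 4 from 143394441 to 144364419 held 5 genes, Pramel1, Pramef8, BC080695, Pramef25 and Gm13119. On chromosome 7 from 104338754 to 104862667, Trim12c was followed by Usp17le, Usp17lb and Usp17la. A run on chromosome 13 from 120263114 to 120318261 held AF067061, BC147527 and Tcstv3, and the Zscan4 genes formed another on chromosome 7. Gca, Csrnp3 and Galnt3 on chromosome 2 (62664327 to 66124793) formed the remaining run of 3 genes. Leaving out the Zscan4 cluster and the symbol families left 32 pairs against a mean of 13.3 in random sets (permutation test, p = 1e-04). That setting still held AF067061, BC147527 and Tcstv3, of which AF067061 and Tcstv3 share sequence with other genes. Some pairs are overlapping models that may count the same reads, and no setting left these out. Timm21, for example, lies within the span of Fbxo15 (chromosome 18, 84935025 to 84981392). Without Em+ replicate 1 there were 744 pairs among 2642 risen genes against a mean of 578 in random sets, and without Em+ replicate 2 there were 199 among 1136 against 107 (permutation test, p = 1e-04 in both).

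**Figure D4:**
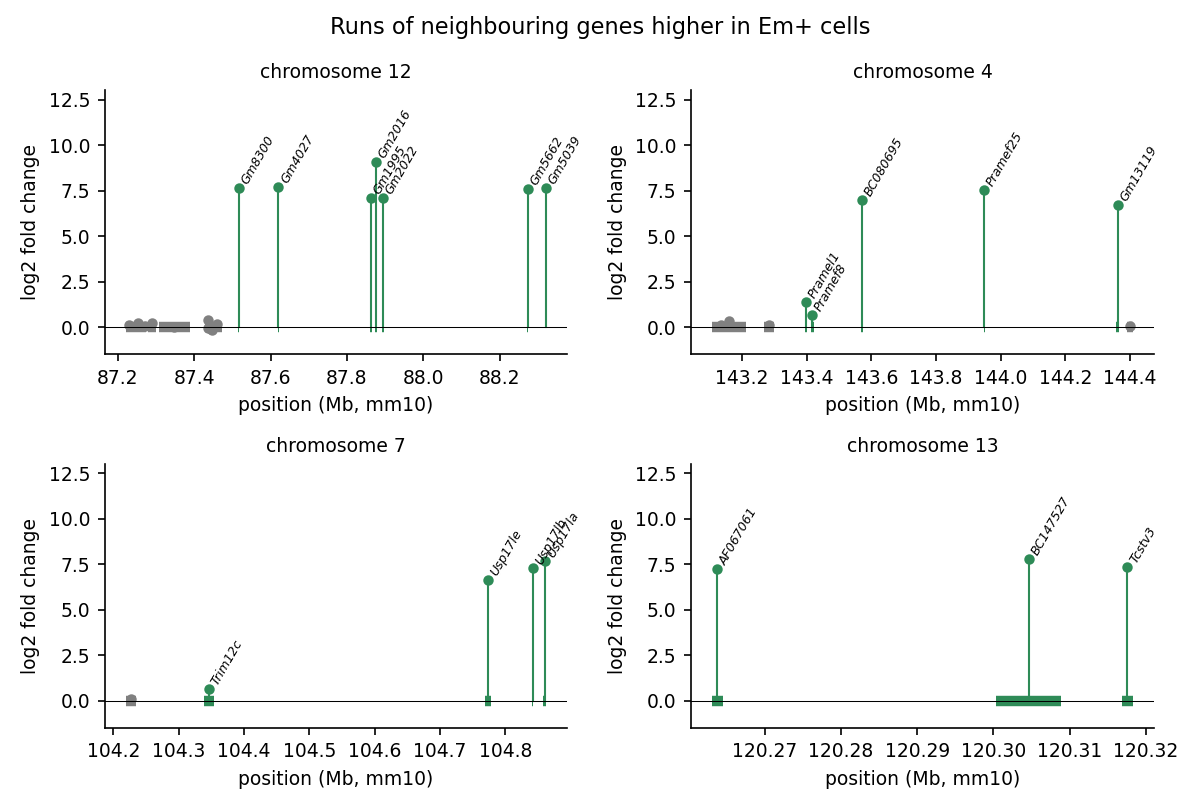
Maps of the longest runs of neighbouring risen genes by position on mm10 chromosomes, each gene drawn with its log2 fold change (Em+ over Em-). The run on chromosome 12 holds 7 genes with a median log2 fold change of 7.62.

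The other transcript annotations gave the same directions for nearly every gene called with RefSeq. With known-gene models, 546 of the 559 were tested, all 546 had the same sign and 417 were called. With ENCODE and Ensembl models, 509 were tested in each, 508 had the same sign in each, and 389 and 388 were called. The exception was Slc27a2, a fatty acid transporter gene (chromosome 2, 126553024 to 126588243). It rose from 12.1 ± 1.81 to 27.6 ± 1.82 CPM with RefSeq (log2 fold change 1.19, SE 0.13, edgeR adjusted p = 0.00201). Its log2 fold change was −0.08 in both the Ensembl (adjusted p = 0.815) and ENCODE (adjusted p = 0.792) tables, and over 24 alternatives the adjusted p ran from 6.95e-10 to 0.815.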

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

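Limma on log2(FPKM + 1), DESeq2, filterByExpr, library totals only, and the neighbour count under other calls, tables, filters and left-out libraries, were chosen after the data were seen. The Zscan4 median stayed above 0 with all tested members called in every alternative, from 3.57 after quantile scaling to 7.49 without Em- replicate 2. The neighbour count stayed past its threshold in every alternative, with 13 to 744 pairs (permutation test, p = 1e-04 in each). No gene of the 559 was called in the opposite direction in any alternative. Scaling choices gave 573 (median-ratio), 623 (upper-quartile) and 571 calls (without small RNAs), and the highest transcript 574. The number of called genes moved by more than 1.5 times, against 460 higher and 99 lower, with limma on log2(FPKM + 0.1) (269, 215 higher, 54 lower), log2(FPKM + 0.5) (280, 220, 60) and log2(FPKM + 1) (293, 226), with quantile scaling (242, 218, 24), limma without trend (182, 157, 25), no filter (1178, 887, 291), a mean FPKM of at least 0.1 (1109, 847, 262) or 5 (171, 148, 23), filterByExpr (1247, 942, 305), a log2 fold change of at least 1 (172, 170, 2) and a test against a larger change than 0 (152, 152 higher, 0 lower). Fewer genes are tested with the filter at 5, and the last 2 demand a larger change; the cause of the others was not tested. Falls alone moved with robust fitting (167), DESeq2 (151) and library totals only (185). Leaving out 1 library gave 490 to 4992 calls, 457 to 2642 higher and 33 to 2350 lower; fewer samples then set the spread.

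With the replicate number as a block there were 1552 calls (1090 higher, 462 lower). The deviations of same-numbered libraries had a correlation of 0.003 across genes, which gave no sign of pairing by number. With 2 libraries in each fraction this value cannot exclude that same-numbered libraries shared a culture or sort.

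The number of called lists moved from 12 to 2 with an estimated correlation, 7 with fry, 26 without a filter and 6 with a mean FPKM of at least 5, and ran from 10 to 16 with 1 library left out. The small nucleolar RNA list was not called before and was called higher after quantile scaling (median 0.0823, adjusted p = 2.47e-04; over its alternatives the adjusted p ran from 2.47e-04 to 0.945), and Slc27a2 was at −0.0786 with Ensembl and −0.0843 with ENCODE models; the cause was not tested. Of the other values of named genes under alternatives 3548 kept direction and side of the threshold, 201 lost the call and 240 gained it, and for lists the numbers were 762, 45 and 36. Depth limits genes with few Em- reads, whose folds rest on counts under 10 there.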

Other observations

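The tests chosen only after the result was seen are those of Rn45s, Gm26924, Gm26917 and AA474408, of the histone and ribosomal protein lists without Em+ replicate 2, and of how many mostly unique 2-cell-stage genes were called.

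Genes outside the lists also rose, and those named here were chosen after their values were seen. Cacna1s, a subunit of a voltage-gated calcium channel, rose from 1.26 ± 0.000412 to 69.2 ± 16.2 CPM (log2 fold change 5.76, SE 0.23, edgeR adjusted p = 7.96e-06). Spesp1, which encodes a sperm protein, rose from 3.20 ± 0.133 to 45.4 ± 2.09 CPM (3.82). Cntnap3, a contactin-associated protein gene, rose by 5.69 on the log2 scale (6.61 without Em- replicate 1). Slfn2, a schlafen gene, had 2 Em- reads, a 148-fold ratio of counts with a counting interval from 40.6 to 1229, and log2 fold changes of 10.13 without Em- replicate 1 and 6.09 without Em- replicate 2. Some genes of DNA repair and replication rose too. They include the endonuclease gene Ercc4, from 14.5 ± 0.0258 to 73.4 ± 7.78 CPM (log2 fold change 2.34), Mcm9, from 7.81 ± 0.385 to 31.2 ± 1.29 CPM (2.00), and the nuclease gene Fan1 (1.10). The retinoid receptor gene Rxra rose from 29.0 ± 2.20 to 85.7 ± 7.53 CPM (1.56). DNA repair was not a list fixed in advance and was not tested as a group.

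Most called gene symbols present in the Ensembl table alone were higher in Em+ cells. Of 3367 such tested symbols 114 were higher and 12 were lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of the risen ones 68 had a log2 fold change of at least 3. Some of these symbols name loci that RefSeq holds under another symbol, so the counts partly repeat genes given above. For example, mmu-mir-8109 and mmu-mir-6236 have the coordinates of Mir8109 and Mir6236. Gm21761 had 2182 and 1990 counts in the Em+ libraries against 11 and 18 in the Em- libraries, and Gm7627 had 152 and 134 against 0 in both. Gm8332, inside the run of risen genes on chromosome 12, had 835 and 710 counts against 1 in each Em- library. Kdm4dl, a histone demethylase-like gene, had 354 and 278 against 2 and 3. These 4 were chosen after their values were seen. In the RefSeq table Gm5643 had 8 and 3682 counts in Em+ replicates 1 and 2 and 2 and 9 in the Em- replicates, and was not called (log2 fold change 8.58, SE 2.52, edgeR adjusted p = 0.0992). Of its 21 alternatives 6 called it, with adjusted p from 1.62e-146 to 0.653 over all 21. They were DESeq2 (adjusted p = 0.0222), library totals only (0.0385), the replicate block (1.09e-16), and the fits without Em+ replicate 1 (2.85e-10), Em- replicate 1 (5.54e-135) or Em- replicate 2 (1.62e-146). Without Em+ replicate 2 its log2 fold change was 0.58 (adjusted p = 0.653).

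Lars2 and Mir6236 had the largest falls, and residual ribosomal RNA is a candidate explanation. More of the whole sequence of the Rn45s model (chromosome 17, 39842997 to 39848829) in the Em- libraries is argued against by its log2 fold change. The value was 0.5468 (SE 0.40, edgeR adjusted p = 0.420), although that sign rests on Em+ replicate 2. Rn45s was at −0.09 without that library, far above the falls, and at 0.99 without Em+ replicate 1. Ribosomal RNA sequence outside the model does not enter these values. More of 1 part of ribosomal RNA, inside or outside this model, stays open. Inside its span 2 models moved apart, Gm26924 at −2.375 (SE 0.42, edgeR adjusted p = 0.0167) and Gm26917 at 1.09 (SE 0.38, adjusted p = 0.157). Lars2 and Mir6236 share no 20-base stretch with Gm26924, and other ribosomal RNA sequence was not searched. Reads from sequence that the Lars2 3' end shares with other models also stay open, since Gm15564 (52 shared bases) had −1.642 (SE 0.64, edgeR adjusted p = 0.174) on 7 and 1 against 12 and 15 counts, while AA474408 (41 shared bases elsewhere) had 0.34 (SE 0.21, adjusted p = 0.373) on 169 and 238 against 170 and 185 counts.

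Several of these values depend on single libraries. Lars2 was at −4.24 without Em+ replicate 1 and −2.21 without Em+ replicate 2, and Gm26924 was at −3.29 without Em+ replicate 1. Gm26917 was called without Em+ replicate 1 (1.63, edgeR adjusted p = 7.75e-16), Em+ replicate 2 (0.18, adjusted p = 0.0310) and Em- replicate 1 (1.21, adjusted p = 0.0268), and AA474408 without Em+ replicate 1 (0.63, adjusted p = 0.00117).

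Replication histone and ribosomal protein genes had lower medians in Em+ cells, of −0.35 and −0.18. Em+ replicate 2 as the whole cause is argued against, since the medians without it were −0.2894 and −0.1347 and camera called both lists. Random lists matched on transcript length had medians of −0.1118 (middle 95% from −0.168 to −0.0442) and −0.1075 (−0.161 to −0.0489), and 0% and 0.32% of them lay as low, so length may account for part but not for all of the shift. Lists matched on GC content had medians of −0.02174 and −0.006021, and 0% of either lay as low. No biological explanation was tested, and the lists lost camera's call with an estimated correlation (adjusted p = 0.708 in both).

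The 2-cell-stage list holds families of near-identical copies, so reads shared among copies may spread a rise over genes that did not change. For the 16 members with at least 90% of their 50-base stretches found in no other gene this is argued against as the whole cause, since 11 of them were called higher (edgeR's quasi-likelihood test). Their median log2 fold change was 2.622, between the bounds set beforehand for and against sharing. Among the 22 less unique members 21 were called higher with a median of 7.27, and for these sharing cannot be told apart from a rise of each copy, since the counting program's handling of such reads is not given in the sources used here. Transcription of these genes in Zscan4-positive cells stays a hypothesis for the less unique members.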
